A study of Homo sapiens with 20 samples.

How the data were processed

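The samples were bulk poly(A) RNA-seq libraries of macrophages and adipocytes that had been made from the same human induced pluripotent stem cell line, WTC11, and cultured either alone or on opposite sides of a permeable insert. Per the labels' protocols, the fragment inserts were 250 to 300 bp. The deposited values are raw read counts per Ensembl gene, in 1 table with 1 column per library. Per the submitters' processing notes, CASAVA, STAR 2.7.2b and the GRCh38 genome build were used. The counting tool, its strand setting and the annotation release are not given in the sources used here. All 58735 gene identifiers of the table are those of GENCODE release 29, and 58207 of them had an official symbol in the gene name table. Coordinates are those of that release on GRCh38.

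The 20 libraries fall into 7 groups by their titles. Each title calls its library a biological replicate, and every group has 3 libraries except M1 macrophages cultured alone, which has 2, although the design text states 3 per condition. Nothing in the labels says whether the replicates came from separate differentiations, so p-values measure the spread between these cultures of 1 cell line. No pair of replicate libraries agreed within sampling noise: the chi-square per degree of freedom, over genes with at least 20 counts in the pair, was 2.75 to 35.9. No library was therefore counted as a duplicate.

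Adipocyte libraries (9) and macrophage libraries (11) were fitted separately, each with all of its groups, so that the groups of a cell type share 1 estimate of the spread. Genes were kept with edgeR's filterByExpr (minimum count 10), which left 17121 genes in adipocytes and 16892 in macrophages. Counts were scaled by TMM and tested with edgeR 4.0.16 (robust quasi-likelihood F test, R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM values (counts scaled to the library size) were computed from the deposited counts with TMM-scaled library sizes, and principal components from log2 CPM with a prior count of 2. There were 8 contrasts: 3 among adipocyte groups, 4 between macrophage groups and 1 interaction, which tests whether the response to coculture differed between M1 and M2 macrophages. Genes named as changed have this adjusted p, unless another test is named.

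Before the data were examined, 43 gene lists were fixed: signalling and inflammatory pathways, metabolic pathways, adipocyte and macrophage states, and markers of other cells that the cultures could hold. A list was tested if at least 5 of its members were tested, or 3 for markers of other cells. The test was camera from limma 3.58.1 with its preset correlation of 0.01, adjusted over the lists of a contrast, which asks whether the members moved more to 1 side than other genes did. For each list the text gives the members past the threshold over all genes, and the number when p-values are adjusted over the list alone. Camera with a correlation estimated from the data, and fry, which asks only whether members move on balance to 1 side, were run as alternatives. The genes to name were also set in advance. For each pairwise contrast they are the 6 genes with the highest and the 6 with the lowest log2 fold change among genes with an adjusted p under 0.05, a mean of at least 5 CPM in 1 of the groups, an official symbol and no overlap between the groups' libraries. They are joined by the 3 members with the lowest adjusted p of each list past its threshold, and by a fixed panel of adipocyte or macrophage genes reported whether or not they passed. About 30 at most are printed for each contrast, and a gene outside this rule is said to be so. Some genes that the rule names are not reported here.

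A gene with 0 counts in a group was given a lower bound on its fold, from a floor of 3 counts over the group's summed library sizes. For 1 to 3 counts, the ratio of the rates is given with its exact 95% counting interval. Floors and counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. The share of a gene that lies under another annotated gene was computed with bedtools 2.31.1, and values of genes with at least 20% overlap are uncertain because the strand setting is unknown. Members of near-identical families (HLA, GBP, metallothionein and SAA genes) are likewise uncertain where reads could be shared. In the adipocytes, PPARG counts can include reads of the PPARG transgene that the protocol delivers.

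The alternatives set in advance were DESeq2 1.42.0 and limma voom with sample quality weights in place of edgeR, DESeq2-style size factors in place of TMM, no low-count filter, a stricter filter of at least 1 CPM in at least 3 libraries, a fit of only the groups compared, the replicate number as a block, leaving out each replicate, and the other list tests. Leaving out both M2 libraries that stood apart was added after the data were seen. The same scripts were tested on simulated counts with 200 genes changed by 1.5-, 2- or 4-fold. At a 2-fold change edgeR recovered 74.6% of changed genes for adipocytes with M1 against alone, 73.1% for adipocytes with M2 against alone, 77.6% for adipocytes with M1 against M2, 41.8% for M1 and 59.7% for M2 macrophages with coculture, 41.8% for M1 against M2 alone, 47.8% for M1 against M2 in coculture, and 22.4% for the interaction. Of the calls on simulated counts, 8 of 159, 13 of 158, 8 of 153, 2 of 92, 6 of 118, 4 of 94, 11 of 111 and 6 of 65 were false, in the same order. Every column of the table belongs to 1 of the 20 libraries and all were used.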

Results

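RNA was sequenced from macrophages and adipocytes that shared 1 genome, because both were differentiated from WTC11, a human induced pluripotent stem cell line. Macrophages were grown from stem cell-derived blood progenitors with M-CSF at 100 ng/mL, with a stated efficiency of about 70%, and are called M2 here as in the labels. M1 macrophages were the same cells after 1 day with lipopolysaccharide (LPS, a bacterial cell wall component) at 10 ng/mL and an interferon at 20 ng/mL, whose type is lost from the label. Adipocytes came from stem cell-derived mesenchymal cells that carried an inducible gene for PPARG, the master transcription factor of fat cells. In coculture, macrophages sorted for the leukocyte surface protein CD45 sat in permeable inserts above adipocytes in 24-well plates for 2 days, in 0.3 mL of medium with M-CSF at 50 ng/mL. Monocultures of either cell type were kept in the plate, so cocultured and lone macrophages also differed in the surface they grew on. Whether lone macrophages were sorted for CD45 too is not given in the sources used here, so the sort may be a further difference in every comparison of cocultured with lone macrophages.

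The adipocyte libraries were 3 cultured alone, 3 cocultured with M1 and 3 cocultured with M2 macrophages. The macrophage libraries were 2 of M1 alone, 3 of M2 alone, 3 of M1 with adipocytes and 3 of M2 with adipocytes. Total counts per library ran from 8546377 (M2 with adipocytes, replicate 3) to 17693291 (adipocytes with M2, replicate 1). They ran from 12842920 to 15408198 in adipocytes alone, from 14042477 to 15044167 with M1 and from 11072981 to 17693291 with M2. In macrophages they ran from 9400908 to 12539032 in M1 alone, 9820474 to 10427831 in M2 alone, 10169940 to 12952576 in cocultured M1 and 8546377 to 15490342 in cocultured M2. Mitochondrially encoded genes took 7.6%, 7.5% and 7.9% of counts on average in adipocytes alone, with M1 and with M2. The average was 3% in M1 alone, 2.9% in cocultured M1, 5.8% in M2 alone and 4.4% in cocultured M2, and replicate 2 of M2 alone had 8.5%. The most abundant transcript was FN1 (fibronectin) in adipocytes alone and with M1, SCD (a fatty acid desaturase) in adipocytes with M2, and FTH1 (ferritin heavy chain) in all M1 libraries. Values are mean CPM ± SD with the group sizes above, fold changes are log2 ± SE, and adjusted p-values are from edgeR's quasi-likelihood test for genes and from camera for lists.

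**Figure D1:**
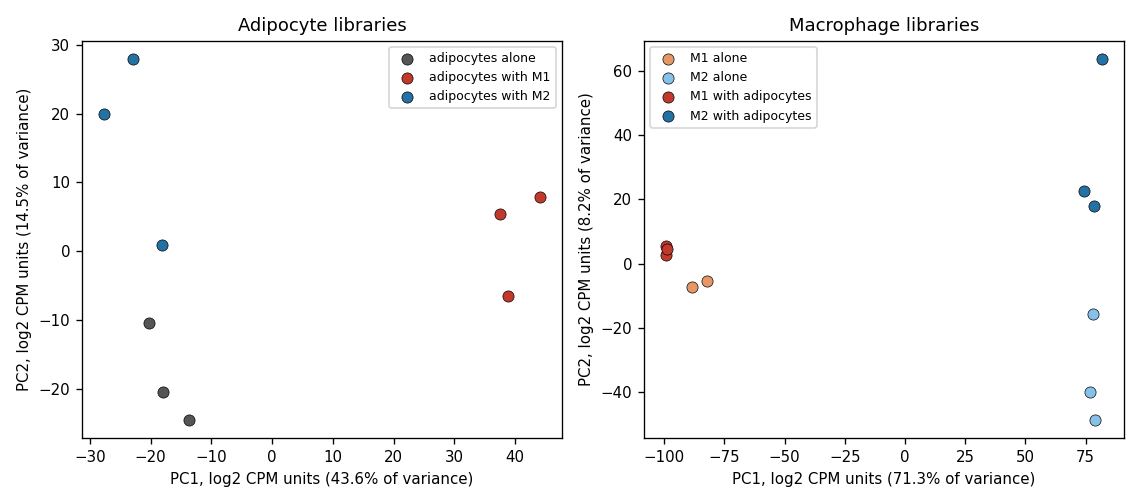
Principal components of log2 CPM for adipocyte (left) and macrophage (right) libraries, 1 point per library, coloured by group. PC1 holds 43.6% of the variance in adipocytes and separates those with M1 from both other groups; it holds 71.3% in macrophages and separates M1 from M2, and replicate 3 of M2 with adipocytes lies at 63.8 on PC2 against 18.1 and 22.5 for the other 2.

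The first comparison asked what proinflammatory macrophages changed in adipocytes across the insert. Adipocytes with M1 had higher transcripts of chemokines, interferon gamma targets and antigen presentation genes, and lower transcripts of several lipid-handling genes. SOD2, a mitochondrial superoxide dismutase induced by inflammatory signals (ENSG00000112096, chromosome 6, 159669057 to 159745186), rose from 85.9 ± 6.79 to 1110 ± 61.3 CPM (3.69 ± 0.09, adjusted p = 1.31e-17). CXCL8, a neutrophil chemoattractant, rose from 2.34 ± 0.311 to 108 ± 19.8 CPM (5.51 ± 0.15, adjusted p = 1.84e-15). Adiponectin (ADIPOQ, chromosome 3, 186842690 to 186858463), a hormone of fat cells, fell from 213 ± 21.5 to 112 ± 9.06 CPM (-0.93 ± 0.15, adjusted p = 0.0023), with 46.2% of the gene under another annotated gene. In all, 1074 genes were higher and 528 lower of 17121 tested, of which 310 and 80 differed by over 2-fold.

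Of 33 tested genes of the NF-kB and cytokine list, 32 rose (32 adjusted over the list alone; camera adjusted p = 4.58e-48). They include IL6, at 36.9 ± 2.66 against 4.54 ± 1.08 CPM, CCL2, which attracts monocytes, at 59.4 ± 5.09 against 11.5 ± 2.7 CPM, and ICAM1, a leukocyte adhesion molecule, at 283 against 24.9 CPM. Other genes overlap 20.7% of IL6 and 23.6% of ICAM1. Of 26 interferon gamma targets 22 rose (25 adjusted over the list alone; adjusted p = 9.46e-40), and several had almost no counts in adipocytes alone. GBP5, an interferon-induced GTPase, was at least 814-fold higher, at 58 ± 7.76 CPM against 0 counts. CXCL11 had 1 count in adipocytes alone and was 1160-fold higher (interval 207 to 45700), CXCL10 had 3 counts there and was 726-fold higher (248 to 3520), and IDO1, which degrades tryptophan, had 1 count there and was 584-fold higher (104 to 23100). Of the 32 genes of the general interferon response 20 rose (32 adjusted over the list alone; adjusted p = 5.64e-26, adjusted p = 0.0975 with an estimated correlation).

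All 18 tested genes of MHC class I antigen presentation rose, by a median of 1.14 (18 adjusted over the list alone; adjusted p = 5.51e-27). PSMB9, a subunit of the immunoproteasome, rose from 5.99 to 39.4 CPM, and ERAP2, which trims peptides, from 87.1 to 198 CPM. In the class II list 4 of 7 rose (4 adjusted over the list alone; adjusted p = 1.33e-07), led by CD74, the invariant chain, from 0.193 to 48.3 ± 6.06 CPM. Acute phase and complement genes rose in 7 of 14 (7 adjusted over the list alone; adjusted p = 4.01e-09), among them SAA1, from 1.45 to 23.8 CPM, and the complement protease C1S, from 57.7 to 181 CPM. Of 5 tested macrophage markers CD74 passed and the other 4 did not (1 adjusted over the list alone; adjusted p = 0.0206, adjusted p = 0.22 with an estimated correlation; 0.115 without replicate 1 of adipocytes alone), and C1QA was at 1.07 against 0.675 CPM.

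Groups outside immunity also rose. In the glycolysis and hypoxia list 24 of 31 genes were higher (25 adjusted over the list alone; median 0.39, adjusted p = 1.32e-17), with ENO2, a glycolytic enolase, at 0.9 ± 0.09 and ADM, a vasodilator peptide, at 264 against 162 CPM. Immediate early genes were higher in 17 of 20 (18 adjusted over the list alone; median 0.58, adjusted p = 4.17e-16), including NR4A1 (0.97) and JUNB (0.82). The unfolded protein response rose in 13 of 24 (16 adjusted over the list alone; median 0.31, adjusted p = 5.38e-10), with HYOU1, a chaperone of the endoplasmic reticulum, at 160 against 125 CPM. Among extracellular matrix genes 13 of 29 rose and 1 fell (16 and 1 adjusted over the list alone; adjusted p = 1.6e-08, adjusted p = 0.0813 with an estimated correlation), including LOX, which crosslinks collagen, at 403 against 262 CPM. Matrix metalloproteinases went both ways, with 11 of 18 higher and 2 lower (12 and 2 adjusted over the list alone; adjusted p = 2.08e-05). MMP3 rose by 3.78 ± 0.39 and MMP8 fell by 1.87.

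Part of the lipid genes were lower, and no lipid list passed with an estimated correlation. Fatty acid and triglyceride synthesis genes were lower in 7 of 24 and higher in 0 (12 adjusted over the list alone; median -0.28, adjusted p = 2.67e-06, adjusted p = 0.388 with an estimated correlation). ACLY, which makes cytosolic acetyl-CoA, stood at 898 against 1370 CPM (-0.61 ± 0.11, adjusted p = 0.000534). Of the adipocyte identity list 5 of 20 fell and 1 rose (8 and 1 adjusted over the list alone; median -0.3, adjusted p = 0.000293, adjusted p = 0.485 with an estimated correlation). Of the lipolysis list 6 of 18 fell (8 adjusted over the list alone; median -0.37, adjusted p = 2.08e-05, adjusted p = 0.354 with an estimated correlation). The lipid droplet protein CIDEC fell from 179 to 97 CPM (-0.89 ± 0.11, adjusted p = 3.67e-05), and GPD1, which makes glycerol phosphate, from 607 to 375 CPM. PLIN1, which coats lipid droplets, fell from 317 to 202 CPM (adjusted p = 0.00716), a call lost without replicate 2 of adipocytes with M1 (adjusted p = 0.0503) or without replicate 3 (0.0581). PLIN2, another droplet coat protein, rose from 158 to 302 CPM. In the same libraries mesenchymal stromal markers were higher in 8 of 20 (11 adjusted over the list alone; median 0.26, adjusted p = 1.21e-06, adjusted p = 0.0305 with an estimated correlation). Neural and epithelial markers were lower in 2 of 8 (4 adjusted over the list alone; median -0.36, adjusted p = 0.0099, adjusted p = 0.0844 with an estimated correlation). Ribosomal protein genes had a median change of 0.12 with 0 of 24 past the threshold (0 adjusted over the list alone; adjusted p = 0.0454, adjusted p = 0.664 with an estimated correlation). That call was lost without replicate 2 of adipocytes alone (adjusted p = 0.687), and its direction turned without replicate 3 of adipocytes with M1 (0.93).

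The insulin signalling list was borderline, with 2 of 25 genes lower and 1 higher (2 and 1 adjusted over the list alone; median -0.16, adjusted p = 0.0457, adjusted p = 0.449 with an estimated correlation). It lost its call without replicate 1 (adjusted p = 0.0519) or 2 (0.129) of adipocytes alone and without replicate 3 of adipocytes with M1 (0.123). The glucose transporter SLC2A4 stood at 3.48 ± 0.901 against 5.88 ± 1.25 CPM (adjusted p = 0.103), the insulin receptor substrate IRS1 at 154 ± 12 against 175 ± 5.13 CPM (0.111) and IRS2 at 97.2 against 92 CPM (0.609). SLC2A4 passed with no low-count filter (adjusted p = 0.00629) and with only the groups compared in the fit (0.0352). PPARG was at 785 ± 134 against 987 ± 46.7 CPM (-0.33 ± 0.14, adjusted p = 0.185; 0.0251 without replicate 1 of adipocytes with M1, 0.00218 with no low-count filter and 0.0334 with only the groups compared) and the lipid carrier FABP4 at 1540 in both groups (adjusted p = 0.999). The leptin gene LEP had 1 count in the 6 libraries and was not detectable at this depth.

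**Figure D2:**
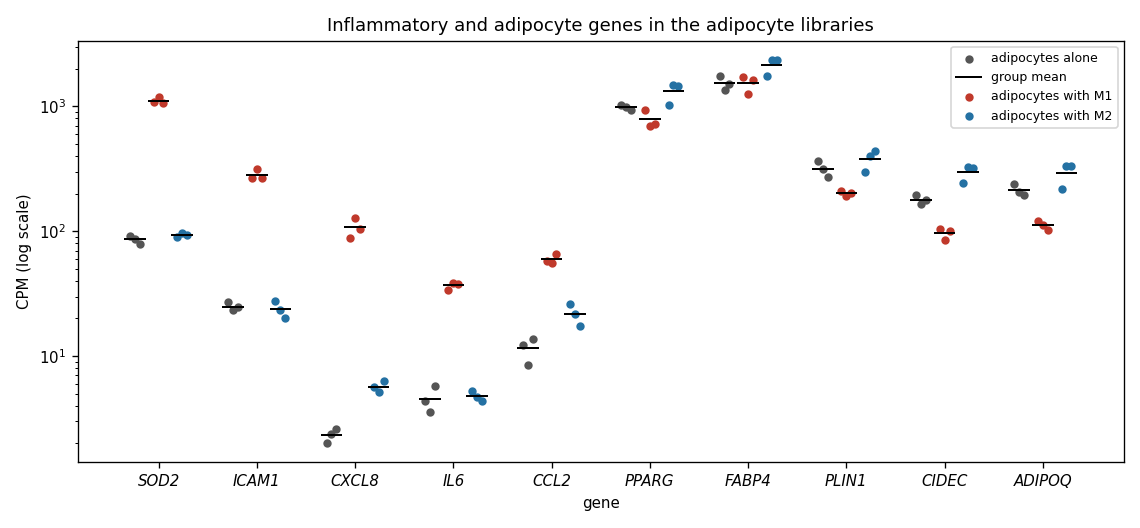
CPM on a log axis of 5 inflammatory and 5 adipocyte genes in each adipocyte library (points) with group means (bars), for adipocytes alone, with M1 and with M2. The mean of SOD2 is 1110 CPM with M1 against 85.9 alone and 92.8 with M2; the mean of CIDEC is 97 CPM with M1, 179 alone and 297 with M2.

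The same question was put to unpolarized macrophages. In adipocytes with M2 310 genes were higher and 476 lower, of which 16 and 30 differed by over 2-fold. This count of 786 was below the 1602 of adipocytes with M1, but it was 1648 without replicate 1 of adipocytes with M2. Of 20 immediate early genes 14 rose and of 10 smooth muscle genes 7 fell, and neither list passed with an estimated correlation (adjusted p = 0.0867 and adjusted p = 0.173). NR4A1, a nuclear receptor induced within minutes of stimulation (chromosome 12, 52022832 to 52059507), rose from 20.4 ± 1.75 to 45.3 ± 2.32 CPM (1.15 ± 0.1, adjusted p = 3.34e-06). SYNPO2, an actin-binding protein of muscle, fell from 211 ± 10.2 to 123 ± 11.9 CPM (-0.78 ± 0.08, adjusted p = 1.12e-05).

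Of 20 immediate early genes 14 rose (18 adjusted over the list alone; median 0.58, adjusted p = 2.07e-17, adjusted p = 0.0867 with an estimated correlation), including the transcription factors EGR2 (1.19 ± 0.13) and JUNB (0.69 ± 0.08). In the NF-kB list 6 of 33 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 7.15e-05, adjusted p = 0.192 with an estimated correlation). CXCL8 rose from 2.34 to 5.71 CPM (adjusted p = 0.000667), CXCL1 from 2.38 to 6.14 CPM (0.00104) and CCL2 from 11.5 to 21.7 CPM (0.00747). IL6 was at 4.75 against 4.54 CPM (adjusted p = 0.911). No interferon response gene of 32 passed (0 adjusted over the list alone; median -0.18, adjusted p = 0.61). Without single libraries the list went past the threshold in either direction: upward without replicate 2 of adipocytes alone (adjusted p = 0.0374), downward without its replicate 3 (0.0311) and without replicate 3 of adipocytes with M2 (0.0165). Of 10 smooth muscle genes 7 fell (8 adjusted over the list alone; median -0.56, adjusted p = 4.93e-08, adjusted p = 0.173 with an estimated correlation), among them CNN1 (calponin, -0.88 ± 0.11) and ACTG2 (-0.63 ± 0.08). Of 29 matrix genes 8 fell (9 adjusted over the list alone; median -0.12, adjusted p = 6.85e-06, adjusted p = 0.416 with an estimated correlation), such as CCN2, a growth factor of connective tissue, from 1860 to 1260 CPM. Outside these lists ANKRD1, a cardiac and stretch-responsive gene, fell from 167 to 73.1 CPM and SYT16 from 11.9 to 3.54 CPM.

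Lipid lists were shifted upward in adipocytes with M2. The adipocyte identity list had 6 of 20 genes higher (15 adjusted over the list alone; median 0.45, adjusted p = 2.61e-08, adjusted p = 0.472 with an estimated correlation). Fatty acid and triglyceride synthesis had 2 of 24 (12 adjusted over the list alone; median 0.27, adjusted p = 2.55e-06, adjusted p = 0.503 with an estimated correlation). Cholesterol synthesis had 4 of 23 (14 adjusted over the list alone; median 0.27, adjusted p = 2.32e-06, adjusted p = 0.518 with an estimated correlation). CIDEC rose from 179 to 297 CPM (0.72 ± 0.11, adjusted p = 0.000886), PLIN2 from 158 to 241 CPM, and ANGPTL4, an inhibitor of lipoprotein lipase, from 130 to 223 CPM. ADIPOQ was at 293 ± 65 against 213 ± 21.5 CPM (adjusted p = 0.121) and PPARG at 1330 ± 258 against 987 ± 46.7 CPM (0.109). Both passed in other settings: without replicate 1 of adipocytes with M2 (ADIPOQ adjusted p = 1.54e-05, PPARG 0.000333), with limma voom (0.00397 and 0.00999) and with no low-count filter (1.02e-06 and 3.94e-05). ADIPOQ also passed with DESeq2 (0.0081). The number of genes changed, 786, rested on single libraries: it was 1648 without replicate 1 of adipocytes with M2, 335 without its replicate 2, 303 without its replicate 3, and 355 and 442 without replicates 2 and 3 of adipocytes alone. It was 1318 with limma voom and 1211 with no low-count filter. In the same libraries neural and epithelial markers were lower as a set, with 0 of 8 past the threshold (5 adjusted over the list alone; median -0.34, adjusted p = 0.0104, adjusted p = 0.301 with an estimated correlation). Ribosomal protein genes had a median change of 0.08 with 0 of 24 past the threshold (0 adjusted over the list alone; adjusted p = 0.0369, adjusted p = 0.91 with an estimated correlation). That call was lost without replicate 2 of adipocytes alone (adjusted p = 0.907) or replicate 1 (0.113) or 3 (0.137) of adipocytes with M2.

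**Figure D3:**
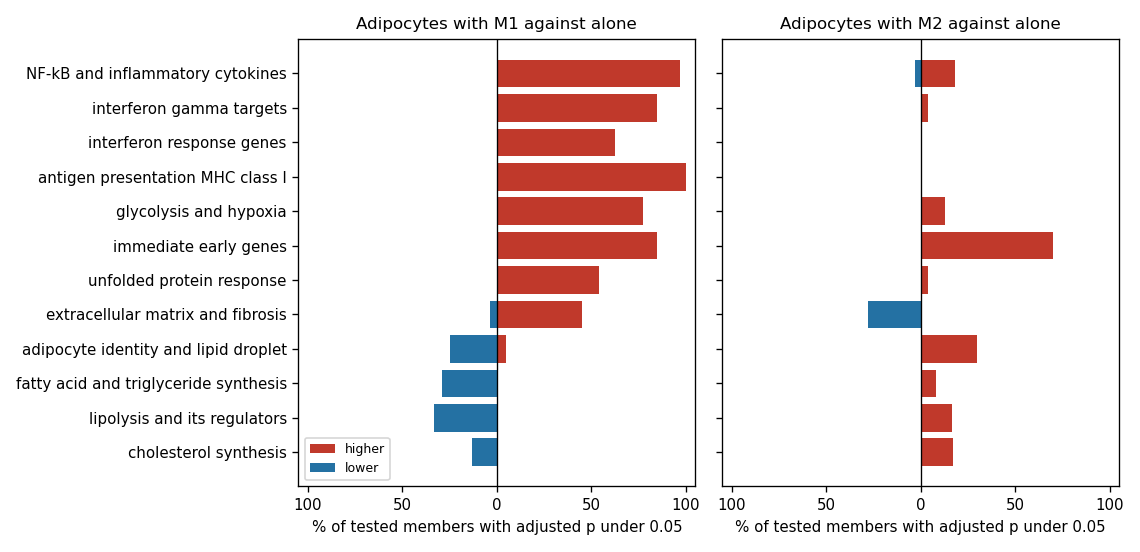
Share of tested members of 12 gene lists with an adjusted p under 0.05, drawn to the right where higher and to the left where lower, for adipocytes with M1 (left) and with M2 (right) against adipocytes alone. With M1, 32 of 33 NF-kB genes were higher and 7 of 24 fatty acid and triglyceride synthesis genes lower; with M2, 14 of 20 immediate early genes were higher and 8 of 29 matrix genes lower.

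Set directly against each other, adipocytes with M1 and with M2 differed in 2678 genes, 1589 higher and 1089 lower with M1, of which 366 and 175 differed by over 2-fold. The NF-kB and matrix lists were higher with M1, and 4 lipid lists were lower but did not pass with an estimated correlation (adjusted p = 0.192 to 0.329). ADIPOQ stood at 112 ± 9.06 with M1 against 293 ± 65 CPM with M2 (-1.39 ± 0.15, adjusted p = 8.86e-05) and CIDEC at 97 against 297 CPM (-1.61 ± 0.11, adjusted p = 2.9e-08). PPARG was lower with M1 (-0.75 ± 0.14, adjusted p = 0.00178), as was SLC2A4, at 3.48 against 7.8 CPM (-1.14 ± 0.26, adjusted p = 0.00572). IRS2 did not differ past the threshold (-0.01, adjusted p = 0.963). IRS1 and FABP4 were past it and lower with M1, but both calls were lost in some settings. Without replicate 3 of adipocytes with M1, IRS1 was at -0.18 (adjusted p = 0.109) and FABP4 at -0.53 (0.0729). Mesenchymal stromal markers were higher with M1 in 11 of 20 and lower in 1 (12 and 1 adjusted over the list alone; adjusted p = 0.000182, adjusted p = 0.0822 with an estimated correlation). The number of genes fell to 1772 without replicate 2 of adipocytes with M2.

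Of the adipocyte identity list 16 of 20 were lower with M1 (18 adjusted over the list alone; median -0.75, adjusted p = 2.45e-11, adjusted p = 0.223 with an estimated correlation). The same held for 17 of 24 fatty acid and triglyceride synthesis genes (21 adjusted over the list alone; median -0.52, adjusted p = 2e-12, adjusted p = 0.205 with an estimated correlation), such as ACLY (-0.99 ± 0.11). Of the lipolysis list 14 of 18 were lower (16 adjusted over the list alone; median -0.68, adjusted p = 1.31e-09, adjusted p = 0.192 with an estimated correlation), including PNPLA2, the first triglyceride lipase, at 826 against 1590 CPM. Of the cholesterol synthesis list 16 of 23 were lower (18 adjusted over the list alone; median -0.37, adjusted p = 2.81e-08, adjusted p = 0.329 with an estimated correlation), including MVD (-0.91). Of 29 matrix genes 23 were higher with M1 (27 adjusted over the list alone; median 0.45, adjusted p = 5.56e-16), with LOX at 403 against 207 CPM. Smooth muscle genes were higher in 9 of 10 (9 adjusted over the list alone; median 0.61, adjusted p = 2.7e-07, adjusted p = 0.0527 with an estimated correlation), led by MYOCD, a coactivator of smooth muscle genes, at 37.9 against 6.92 CPM (2.46 ± 0.17). Immediate early genes, which rose in both cocultures, did not differ between them as a set (median 0.04, adjusted p = 0.612). With M1 3 of 20 were higher and 2 lower (4 and 3 adjusted over the list alone). No group had adipocytes under an insert without macrophages, so changes common to both cocultures cannot be tied to the macrophages. NF-kB genes were higher in 31 of 33 (31 adjusted over the list alone; adjusted p = 1.2e-34). GBP5 was at least 837-fold and CXCL10 at least 752-fold higher with M1, both with 0 counts with M2. Among the lowest with M1 were the calcium channel gene CACNA1I, at 1.53 against 10.9 CPM, NEUROG3, a neurogenic and endocrine transcription factor, at 11.6 against 53.3 CPM, and HES6, at 7.24 against 31 CPM.

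Macrophages cultured alone were compared to see how the M1 and M2 states differed without adipocytes. M1 and M2 macrophages differed in 6302 of 16892 genes, 3315 higher and 2987 lower in M1, and the M1 cells carried cytokine, interferon gamma and antigen presentation transcripts. IDO1 (chromosome 8, 39902275 to 39928444) was at 1810 ± 177 CPM in M1 and at 0 counts in M2, at least 20300-fold higher. The cytokine IL1B was at 2270 ± 149 against 37.8 ± 3.25 CPM (5.91 ± 0.19, adjusted p = 1.79e-13) and TNF at 65.3 against 1.92 CPM (5.09 ± 0.34, adjusted p = 6.09e-09). The mannose receptor MRC1, an M2 marker, was at 85.7 against 1230 CPM (-3.85 ± 0.24, adjusted p = 8.71e-10). The count fell to 4001 without replicate 1 of M1 alone.

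Of the NF-kB list 37 of 38 genes were higher in M1 (37 adjusted over the list alone; adjusted p = 1.8e-29), and of interferon gamma targets 27 of 29, with 2 lower (27 and 2 adjusted over the list alone; adjusted p = 2.49e-22). CXCL10 was at 1060 against 0.149 CPM and CCL2 at 1780 against 9.76 CPM. IL6 was at least 753-fold higher, with 0 counts in M2. All 18 MHC class I genes were higher (18 adjusted over the list alone; median 3.24, adjusted p = 4.48e-15), such as the peptide transporter TAP1, at 902 against 24.7 CPM. Of the M2 marker list 14 of 25 were lower and 9 higher (14 and 9 adjusted over the list alone; adjusted p = 0.0123, adjusted p = 0.47 with an estimated correlation). RNASE1 was at 12.1 against 597 CPM, while the scavenger receptor CD163, also on that list, was higher in M1, at 1240 against 742 CPM (0.75 ± 0.17, adjusted p = 0.00253). Lipid-associated macrophage genes were lower in 11 of 23 and higher in 3 (13 and 4 adjusted over the list alone; adjusted p = 0.0124, adjusted p = 0.484 with an estimated correlation), with GPNMB at 2.8 against 440 CPM and the lipid receptor TREM2 lower by 2.35 ± 0.35 on the log2 scale. Cell cycle genes were lower in 24 of 30 (24 adjusted over the list alone; median -2.1, adjusted p = 6.08e-07, adjusted p = 0.368 with an estimated correlation), and CENPF by -4.29 ± 0.56. Ribosomal protein genes were lower in 23 of 24 (23 adjusted over the list alone; median -1.23, adjusted p = 5.55e-08, adjusted p = 0.377 with an estimated correlation). Matrix genes were higher in M1 in 19 of 25 and lower in 2 (19 and 2 adjusted over the list alone; adjusted p = 1.54e-05, adjusted p = 0.285 with an estimated correlation). Mesenchymal markers were higher in 6 of 13 and lower in 1 (6 and 1 adjusted over the list alone; adjusted p = 0.0231, adjusted p = 0.264 with an estimated correlation). THBS1 (thrombospondin) was at 313 against 8.26 CPM. Smooth muscle markers were higher in 3 of 5 (3 adjusted over the list alone; adjusted p = 0.0122, adjusted p = 0.11 with an estimated correlation). Endothelial markers were lower in 4 of 6 and higher in 1 (4 and 1 adjusted over the list alone; adjusted p = 0.0241, adjusted p = 0.285 with an estimated correlation).

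After 2 days with adipocytes M1 macrophages were still far from M2, with 3579 genes higher and 3214 lower. Of these, 2435 were also higher and 1931 also lower in the comparison of lone cultures, and 42 and 44 genes went opposite ways. The 2 comparisons share no library. IL1B was at 2420 against 27 CPM (6.48 ± 0.19, adjusted p = 5.03e-14), CXCL10 at 1940 against 0.132 CPM and MRC1 at 97.3 against 1420 CPM (-3.87 ± 0.2, adjusted p = 5.42e-11). ACOD1, which makes the antimicrobial metabolite itaconate, was at least 2400-fold higher in M1, at 184 CPM against 0 counts. All 35 interferon response genes were higher in M1 (35 adjusted over the list alone; median 3.19, adjusted p = 2.61e-22, adjusted p = 0.0733 with an estimated correlation), against 24 higher and 2 lower in lone cultures (24 and 3 adjusted over the list alone; adjusted p = 3.87e-07, adjusted p = 0.319 with an estimated correlation). Of 30 cell cycle genes 29 were lower in M1 (29 adjusted over the list alone; median -3.37, adjusted p = 1.34e-13, adjusted p = 0.199 with an estimated correlation). CD163, higher in M1 among lone cultures, was lower in M1 in coculture, at 597 against 1080 CPM (-0.86 ± 0.16, adjusted p = 0.000282). The fatty acid receptor CD36 was at 66.2 against 949 CPM and PDK4, which restrains glucose oxidation, at 1.8 against 233 CPM (-7.02 ± 0.31). APOE (0.59, adjusted p = 0.145) and SPP1 (-0.34, adjusted p = 0.158) did not pass, but SPP1 did with limma voom (adjusted p = 0.00208) and without replicate 3 of cocultured M2 (0.0043). Ribosomal protein genes were lower in M1 in 12 of 24 (16 adjusted over the list alone; median -0.53, adjusted p = 0.00101, adjusted p = 0.607 with an estimated correlation). Of markers of other cells, dendritic cell markers were higher in M1 in 7 of 8 (7 adjusted over the list alone; adjusted p = 8.92e-06, adjusted p = 0.0733 with an estimated correlation). Smooth muscle markers were higher in 4 of 5 (4 adjusted over the list alone; adjusted p = 0.00573, adjusted p = 0.0733 with an estimated correlation). Neutrophil markers were higher in 5 of 7 and lower in 1 (5 and 2 adjusted over the list alone; adjusted p = 0.0278, adjusted p = 0.199 with an estimated correlation).

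The next comparison asked what adipocytes changed in M1 macrophages. In cocultured M1 479 genes were higher and 298 lower, and by list 11 of 29 glycolysis and 6 of 20 immediate early genes rose, with 1 and 2 lower, while 7 of 23 lipid-associated macrophage genes fell and 1 rose. These 3 list calls did not pass with an estimated correlation (adjusted p = 0.123, adjusted p = 0.288 and adjusted p = 0.309). PHGDH, the first enzyme of serine synthesis (chromosome 1, 119648411 to 119744226), rose from 0.511 to 30.7 ± 4.77 CPM (6 ± 0.47, adjusted p = 1.08e-06), and PSAT1, the next enzyme, from 1.1 to 29.5 CPM (4.66 ± 0.38). PDK4 (chromosome 7, 95583499 to 95596491) fell from 92.8 to 1.8 CPM (-5.69 ± 0.32, adjusted p = 1.37e-07) and PLIN2 from 86.6 to 16.3 CPM (-2.4 ± 0.2). The count of 777 rested on the 2 libraries of M1 alone: it was 245 without replicate 1 and 222 without replicate 2, and also fell to 475 and 507 without replicates 1 and 2 of cocultured M1. It was 2062 with limma voom and 2278 with only the groups compared in the fit. Ribosomal protein genes had a median change of 0.23 with 0 of 24 past the threshold (0 adjusted over the list alone; adjusted p = 0.0289, adjusted p = 0.885 with an estimated correlation). It was lost without replicate 1 (adjusted p = 0.0997) or 2 (0.0858) of M1 alone or replicate 2 (0.0755) or 3 (0.357) of cocultured M1.

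In the glycolysis and hypoxia list 11 of 29 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 1.53e-13, adjusted p = 0.123 with an estimated correlation), including VEGFA, an angiogenic factor, at 161 against 64.9 CPM and the glucose transporter SLC2A3 at 441 against 197 CPM. Of the M1 marker list 10 of 26 rose (18 adjusted over the list alone; adjusted p = 6.34e-08, adjusted p = 0.165 with an estimated correlation), with IL12B, a cytokine subunit that drives T cells, at 28.7 against 4.73 CPM and GBP5 at 2240 against 819 CPM. Dendritic cell markers rose in 5 of 8 and fell in 1 (6 and 1 adjusted over the list alone; median 0.89, adjusted p = 0.00279, adjusted p = 0.288 with an estimated correlation). Interferon response genes rose in 11 of 35 (20 adjusted over the list alone; median 0.61, adjusted p = 3.43e-10, adjusted p = 0.288 with an estimated correlation). The NF-kB list rose in 8 of 38 and fell in 3 (12 and 4 adjusted over the list alone; adjusted p = 0.0298, adjusted p = 0.46 with an estimated correlation). The call was lost without replicate 2 of M1 alone (adjusted p = 0.223) and without replicates 2 (0.082) or 3 (0.0518) of cocultured M1. IL1A rose from 41.5 to 124 CPM (1.58 ± 0.22), while IL1B was at 2420 against 2270 CPM (adjusted p = 0.883) and TNF at 46 against 65.3 CPM (0.42). TNF was called lower with limma voom (-0.48, adjusted p = 0.0109) and with only the groups compared in the fit (-0.5, adjusted p = 0.00358). Immediate early genes rose in 6 of 20 and fell in 2 (8 and 2 adjusted over the list alone; adjusted p = 1.49e-05, adjusted p = 0.288 with an estimated correlation), with NR4A1 at 40.6 against 2.55 CPM and EGR3 at 55.4 against 4.13 CPM. Oxidative stress genes fell in 6 of 23 (6 adjusted over the list alone; median -0.34, adjusted p = 9.13e-06, adjusted p = 0.288 with an estimated correlation), such as GCLC, which begins glutathione synthesis, from 93.3 to 25.6 CPM. Lipid-associated macrophage genes fell in 7 of 23 and rose in 1 (7 and 1 adjusted over the list alone; median -0.46, adjusted p = 1e-05, adjusted p = 0.309 with an estimated correlation). CD36 fell from 238 to 66.2 CPM, CPT1A, which admits fatty acids to mitochondria, from 90.9 to 36.8 CPM, and CD163 from 1240 to 597 CPM (-1.06 ± 0.17, adjusted p = 0.00125).

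The last comparison of this kind was of M2 macrophages with and without adipocytes. In cocultured M2 1159 genes were higher and 911 lower. Of the lists, 27 of 35 interferon response and 11 of 23 oxidative stress genes fell, the latter with 1 higher, and 19 of 30 cell cycle and 18 of 29 glycolysis genes rose, the latter with 1 lower. These 4 list calls did not pass with an estimated correlation (adjusted p = 0.213, adjusted p = 0.492, adjusted p = 0.737 and adjusted p = 0.213). With fry, in the same order, the adjusted p was 0.000896, 0.00565, 0.0547 and 0.000896. VCAN, a matrix proteoglycan (chromosome 5, 83471465 to 83582303), rose from 18.8 ± 4.37 to 260 ± 71.4 CPM (3.79 ± 0.2, adjusted p = 1.75e-08), and the gelatinase MMP9 from 199 to 1290 ± 336 CPM (2.69 ± 0.18, adjusted p = 1.08e-07). ID3, an inhibitor of helix-loop-helix factors (chromosome 1, 23557918 to 23559794), fell from 114 ± 17.2 to 4.57 ± 1.95 CPM (-4.61 ± 0.25, adjusted p = 2.71e-08) and its relative ID1 from 15.6 to 0.139 CPM. The share of mitochondrial counts was 5.8% alone and 4.4% in coculture. Ribosomal protein genes had a median change of -0.35 with 0 of 24 past the threshold (0 adjusted over the list alone; adjusted p = 0.00215, adjusted p = 0.804 with an estimated correlation; 0.127 without replicate 3 of cocultured M2). The count of 2070 fell to 1149 without replicate 3 of M2 alone and to 1211 with only the groups compared in the fit.

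Of 35 interferon response genes 27 fell and 0 rose (32 adjusted over the list alone; median -1.33, adjusted p = 1.35e-25, adjusted p = 0.213 with an estimated correlation). IFIT2 fell from 38.3 to 5.39 CPM (-2.82 ± 0.35) and OAS2, a sensor of viral RNA, from 122 to 27 CPM (-2.18 ± 0.18). Cell cycle genes rose in 19 of 30 (24 adjusted over the list alone; median 1.24, adjusted p = 1.46e-10, adjusted p = 0.737 with an estimated correlation), including the mitotic kinase PLK1, from 21.5 to 66.4 CPM. Glycolysis and hypoxia genes rose in 18 of 29 and fell in 1 (18 and 2 adjusted over the list alone; adjusted p = 1.88e-09, adjusted p = 0.213 with an estimated correlation), with LDHA (lactate dehydrogenase) at 446 against 103 CPM and P4HA1 at 76.3 against 31.6 CPM. Oxidative stress genes fell in 11 of 23 and rose in 1 (11 and 2 adjusted over the list alone; adjusted p = 5.33e-05, adjusted p = 0.492 with an estimated correlation), such as NQO1, a quinone reductase, from 36.8 to 6.18 CPM. Lysosomal genes fell in 10 of 28 (12 adjusted over the list alone; median -0.22, adjusted p = 0.000287, adjusted p = 0.784 with an estimated correlation), among them LIPA, the acid lipase, from 1750 to 945 CPM. The M2 marker list rose in 6 of 25 and fell in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0115, adjusted p = 0.791 with an estimated correlation). The call was lost without replicate 2 of M2 alone (adjusted p = 0.0737) or of cocultured M2 (0.0519). LYVE1, a marker of perivascular macrophages, rose from 66.2 to 228 CPM and SPP1 (osteopontin) from 4530 ± 502 to 12800 ± 3200 CPM (1.5 ± 0.19). Lipid-associated macrophage genes, a list that includes SPP1, fell in 7 of 23 and rose in 1 (8 and 1 adjusted over the list alone). Their median was -0.33 (adjusted p = 0.00544, adjusted p = 0.791 with an estimated correlation), a fall as in cocultured M1. MRC1 was at 1420 against 1230 CPM (adjusted p = 0.493), CD36 changed by 0.2 (0.339) and IL1B by -0.48 (0.0518). IL1B passed with DESeq2 (adjusted p = 0.00995), limma voom (0.0121), RLE scaling (0.0455), no low-count filter (0.0265) and the stricter filter (0.0496), and without replicate 1 of M2 alone (0.0353) or of cocultured M2 (0.0101).

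The M1 and M2 responses to coculture overlapped in part. Of 283 genes past the threshold in both, 191 went the same way and 92 opposite ways. There were 113 that rose in both, where independent lists would share 32.9. Another 78 fell in both (16.1 for independent lists), 58 rose in M1 and fell in M2 (25.8) and 34 fell in M1 and rose in M2 (20.4). Both states also moved from plate to insert, and lone cells may not have been sorted for CD45. Changes common to both states therefore cannot be tied to the adipocytes. Across all genes, which are not independent replicates, the fold changes correlated with r = 0.083 (rho 0.045). Its jackknife standard error, over libraries within groups, was 0.0443, so it lay less than 2 standard errors from 0, and it was 0.0497 without replicate 3 of cocultured M1 and 0.0542 without replicate 3 of cocultured M2. A test of the difference itself, the interaction, called 1059 genes, 552 with the higher response in M1 and 507 with the higher in M2. Interferon response genes led it, with 29 of 35 higher in M1 and 0 lower (35 adjusted over the list alone; median 1.96, adjusted p = 1.93e-30, adjusted p = 0.349 with an estimated correlation). The 2 adipocyte responses share the control libraries, so their agreement is raised by chance. Their fold changes had r = 0.174 (rho 0.255) and a covariance of 0.0291, while 50 simulations with no effect gave r = 0.503 and a covariance of 0.0242 (0.0222 to 0.0257), a difference of 0.00496. This lay within the jackknife standard error of the covariance, 0.011. Leaving out a control raises the covariance by construction, so each such value was set against its own 20 simulations: over the same genes it was 0.0479, 0.0544 and 0.0467 without replicates 1, 2 and 3 of adipocytes alone, against 0.038, 0.0375 and 0.0392 with no effect, differences of 0.00991, 0.0169 and 0.0074. There were 87 genes higher in both, against 19.4 for independent lists, and 90 lower in both, against 14.7. Opposite directions also exceeded independent lists, with 43 higher with M1 and lower with M2, against 29.9, and 22 the other way, against 9.56. The simulations shared at most 2 genes higher and 1 lower. Since they called at most 6 genes in either comparison, they set no bound on sharing between lists of 1602 and 786 genes. With 3 controls, the controls cannot be split between the comparisons. Part of the excess in the same direction may come from sharing them.

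**Figure D4:**
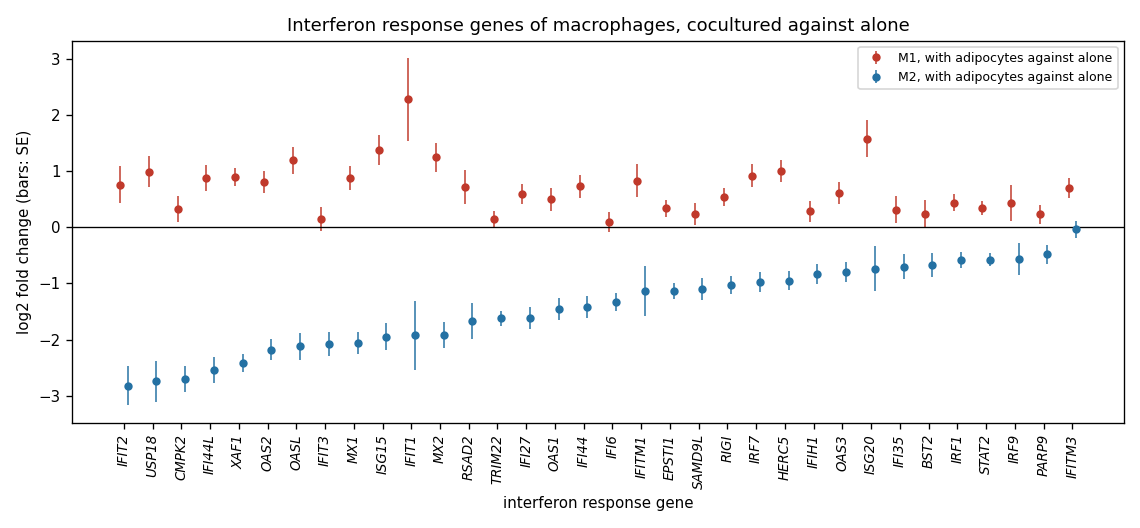
Log2 fold change (points) and SE (bars) of interferon response genes with coculture, in M1 (red) and M2 (blue) macrophages, ordered by the change in M2. Over all 35 genes tested, of which 1 is not drawn, the median is 0.61 in M1 and -1.33 in M2.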

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

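The macrophage RNA, insert against plate and stromal cell tests were chosen only after the result was seen, and the bound of 10 CPM in the last was added later still, before it ran; the count without that bound was added after it. M1 and M2 macrophages responded differently to coculture in 1059 genes by the interaction test of edgeR, which is what brought the values of this part forward. The count rested on the lone M1 libraries: it was 468 without their replicate 1 and 384 without their replicate 2. With limma voom it was 2352. Values are the log2 response in M1 minus that in M2.

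Interferon response genes differed most (adjusted p = 1.93e-30, adjusted p = 0.349 with an estimated correlation; 29 of 35 higher, 35 adjusted over the list alone), with OAS2 at 2.99, MX1 at 2.94 and XAF1 at 3.31. Interferon gamma targets (adjusted p = 7.57e-05, adjusted p = 0.417 with an estimated correlation; 9 of 29 higher and 1 lower, 13 and 1 adjusted over the list alone) included GBP4 at 2.51, PSMB9 at 1.56, SERPING1 at 1.06 and TAP1 at 0.81. The M1 marker list (adjusted p = 2.53e-05, adjusted p = 0.417 with an estimated correlation; 4 of 26 higher, 5 adjusted over the list alone) included IL23A at 3.15 and CD86 at 1.25. Immediate early genes (adjusted p = 0.000108, adjusted p = 0.561 with an estimated correlation; 7 of 20 higher and 1 lower, 11 and 1 adjusted over the list alone) included NR4A2 at 2.79, DUSP1 at 1.4 and JUN at 1.11. The NF-kB list (adjusted p = 0.0133, adjusted p = 0.561 with an estimated correlation; 8 of 38 higher and 5 lower, 13 and 5 adjusted over the list alone) went both ways, with CXCL8 at 1.76 and TNFAIP2 at 1.34 but CCL2 at -2.03, CXCL5 at -2.52 and CCL7 at -4.95; its call was lost without replicate 2 of M1 alone (adjusted p = 0.0544) or replicate 3 of cocultured M2 (0.0519).

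MHC class I genes (adjusted p = 0.00576, adjusted p = 0.561 with an estimated correlation) had 2 of 18 higher and 1 lower (4 and 1 adjusted over the list alone), the latter being the chaperone CALR at -0.78. The class II list (adjusted p = 0.0262, adjusted p = 0.62 with an estimated correlation) had 1 of 10 higher (2 adjusted over the list alone), HLA-DMB at 2.17, and was lost without replicate 2 (adjusted p = 0.0698) or 3 (0.053) of M2 alone or replicate 3 of cocultured M2 (0.11). Cell cycle genes were lower (adjusted p = 1.3e-07, adjusted p = 0.561 with an estimated correlation; 4 of 30, 9 adjusted over the list alone), with PCNA at -0.7, MCM5 at -0.74 and E2F1 at -2.36. Cholesterol synthesis genes were lower (adjusted p = 5.35e-06, adjusted p = 0.561 with an estimated correlation; 2 of 22, 9 adjusted over the list alone). Ribosomal protein genes were higher as a set (adjusted p = 0.000113, adjusted p = 0.623 with an estimated correlation), with 0 of 24 past the threshold (0 adjusted over the list alone).

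Among the genes that differed most upward were ID1 at 7.13, PHGDH at 4.98, ID3 at 4.9, ADAMTS17 at 4.72 and SIDT1 at 4.63, and CYP27B1, which activates vitamin D, stood at 2.5. Those that differed most downward were GAPT at -5.51, CCL7, PDK4 at -4.74, E2F2, which promotes entry to the cell cycle, at -4.03, HS3ST1 at -3.75 and VCAN at -3.74. Of the fixed panel of macrophage genes, SPP1 stood at -1.54, CD163 at -1.6 and CD36 at -2.05. Some of these calls rested on single libraries. Without replicate 1 of M1 alone those of ID1 (adjusted p = 0.0537), IL23A (0.0514), MCM5 (0.172) and TAP1 (0.0648) were lost, and without its replicate 2 those of CYP27B1 (0.0771), HLA-DMB (0.0853), JUN (0.0507), SIDT1 (0.104) and TAP1 (0.141). That of MCM5 was also lost without replicate 2 of cocultured M1 (0.0504). PCNA lost its call without 10 of the 11 single libraries (adjusted p = 0.0501 to 0.192) and kept it without replicate 3 of cocultured M2. CALR lost it without 9 (0.0538 to 0.16) and kept it without that library or replicate 1 of M2 alone. E2F1 lost it without 8 (0.0501 to 0.387) and kept it without replicate 1 of M1 alone or replicate 3 of either coculture. CCL2 lost it without 7 (0.0537 to 0.202) and kept it without replicate 3 of cocultured M1 or any one library of cocultured M2. With no low-count filter CCL2 (0.234) and PCNA (0.0503) did not pass, with limma voom CCL7 did not (-2.68, adjusted p = 0.0643), and without both replicate 2 of M2 alone and replicate 3 of cocultured M2 ID1 (0.0834), CCL2 (0.128) and E2F1 (0.0788) did not.

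The immune genes of adipocytes with M1 could have come from macrophage RNA in the adipocyte wells. Macrophage genes argue against this: CD14, PTPRC, C1QB, FCGR3A, TYROBP and FCER1G allow at most 0.0643% of M1 RNA in any of those libraries, while the 32 NF-kB genes that rose need a median of 9.69% and at least 0.241%. The values also argue against interferon gamma transcribed by the cocultured M1 cells at harvest, since IFNG averaged 0 CPM there. Transcription earlier in the 2 days of coculture was not measured. Cytokines of M1 cells, at 2420 CPM of IL1B and 46 CPM of TNF, and LPS or interferon carried over from polarization both stay open, as no library received M1 medium without cells and the result of the endotoxin assay is not given in the sources used here. A response of the adipocytes to M1 signals remains a hypothesis.

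The fall of interferon response genes in cocultured M2 macrophages could rest on 1 library. All 27 genes remained past the threshold without replicate 3 of cocultured M2 (27) and without replicate 2 of M2 alone (27), which had the high mitochondrial share. This count was not made without each of the other M2 libraries. They include replicate 3 of M2 alone, without which the fewest genes were called for cocultured M2 (1149). The move from plate to insert could lower these genes in any macrophage. In M1 cells, which made the same move, their median rose by 0.61 and the difference was called for 29 of 35. This list was brought forward by that same difference, so the outcome was set in advance and cannot test an effect common to both states. An effect of the insert on M2 cells alone, or of a CD45 sort if lone cells were not sorted, is confounded with coculture and stays open beside a response to adipocytes. Only interferon response genes were weighed here. Glycolysis and hypoxia genes rose in both states, by a median of 0.52 in M1 and 0.69 in M2. For them an effect of the insert common to both stays open too.

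Lone M1 macrophages carried matrix transcripts that lone M2 macrophages nearly lacked, such as COL1A1 at 12.7 against 0 CPM and FN1 at 75.2 against 2.89 CPM. Whether stromal cells in the M1 cultures account for them cannot be told: of 16 matrix and mesenchymal genes abundant in the adipocyte cultures 13 were higher in M1, but these were chosen for under 10 CPM in M2, which favours that outcome, and of the 20 genes without that bound 14 were. The CD45 sort of cocultured cells would remove such cells (whether lone M1 cells were sorted is not given in the sources used here). Cocultured M1 still had COL1A1 at 5.06, 5.69 and 21 CPM, with FN1 at 30.5, 47.3 and 198 CPM in the same libraries. They sat above adipocyte cultures, which alone held COL1A1 at 8520 CPM and FN1 at 28200 CPM. RNA from those wells was not bounded in the macrophage libraries, so the values of cocultured M1 cannot decide the question. Of 5 tested adipocyte markers 0 passed in cocultured M1 against M1 alone (0 adjusted over the list alone; camera adjusted p = 0.963). In cocultured M2 against M2 alone 0 rose and 1 fell past the threshold (camera adjusted p = 0.556), though 4 were positive and the mean log2 fold change was 2.96. Genes did not follow 1 share of the adipocyte-culture profile, since LUM was at 64.3 and 51.7 CPM in lone M1 against 49.5 in adipocytes, and COL1A2 did not pass (6.03 against 4.15 CPM, adjusted p = 0.405), but that profile is assumed and excludes nothing. Stromal cells and induction of matrix genes in the macrophages themselves both stay open.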

How the results depend on the processing

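The alternative without either replicate 2 of M2 alone or replicate 3 of cocultured M2 was chosen after seeing the data; all others were set before the data were examined. Under DESeq2, RLE scaling and the stricter filter every count of genes stayed within 1.5 times the main one. With limma voom the count rose from 786 to 1318 for adipocytes with M2, from 777 to 2062 for cocultured M1 and from 1059 to 2352 for the interaction. With no low-count filter, adipocytes with M2 gave 1211 genes. With only the groups compared in the fit, cocultured M1 gave 2278 and cocultured M2 gave 1211 against 2070. The cause was not tested. Leaving out each library in turn gave 1069 to 1311 genes for adipocytes with M1, 303 to 1648 with M2, 1772 to 3074 for M1 against M2, 222 to 562 for cocultured M1, 1149 to 2584 for cocultured M2, 4001 to 6266 for lone M1 against M2, 5783 to 6677 in coculture and 384 to 1447 for the interaction; a lone M1 library left over is assumed to vary like the other groups. The correlation of the macrophage responses was 0.0497 to 0.121 and the covariance of the adipocyte responses 0.0206 to 0.062. Without both M2 libraries, coculture changed 1862 genes in M2, with 1406 of the 2070 shared, and the interaction called 1512, with 980 of the 1059 shared. Libraries with the same replicate number did not deviate together. Across groups, 0 of 9 such pairs of adipocyte libraries and 1 of 15 of macrophage libraries had a correlation over 0.1 (-0.12 to 0.08 and -0.2 to 0.11). With the number as a block the counts were 1457, 659, 2427, 587, 1747, 5781, 6478 and 845, in the order above with the interaction last, and the correlation of the macrophage responses 0.0443. Reversed directions were few. Ribosomal protein genes in adipocytes with M1 (adjusted p = 0.0454, adjusted p = 0.664 with an estimated correlation) had 0.93 without replicate 3 of that group, over a range of 0.00251 to 0.93. Interferon response genes in adipocytes with M2 (0.61) had 0.0374 without replicate 2 of adipocytes alone, over 0.0165 to 0.967. Fatty acid oxidation genes in lone M1 against M2 (0.534) had 0.00632 with fry; the causes were not tested. Over all genes called, 465 of 777 stayed called for cocultured M1 without its replicate 1. For adipocytes with M2, 298 of 786 stayed called without replicate 3 of that group. Other values were compared for named genes only, most of them picked for large or clear changes, which favours staying past the threshold. Of their values past the threshold 6293 stayed past it and 301 did not. Of those not past it 1073 stayed, 44 moved by more than the spread and 141 passed. Of lists past it 1526 values stayed and 221 did not, and of the others 1147 stayed and 59 passed. With an estimated correlation 30 of 152 list calls held. With fry, which asks only whether members move on balance to 1 side, 111 held and 41 did not. Other splits of 3 against 3 libraries are too few for a share under 0.1 (10 splits, the real one included, of which 1 gave as many genes): the highest other count was 0 for adipocytes with M1, for M1 against M2 in adipocytes, for cocultured M2 and for M1 against M2 in coculture, and 51 against 786 for adipocytes with M2. On counts simulated at these depths and group sizes 1.5-fold changes were recovered in 58.2% of genes for adipocytes with M1 and in 10.4% for cocultured M1.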

Other observations

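The hypothesis tests of this part were written after the named genes had been seen. In adipocytes with M1, CHI3L1, a chitinase-like protein, rose from 32.5 to 208 CPM and FAP, a surface protease of activated fibroblasts, from 26.6 to 42.4 CPM. The cytokine LIF, chosen here after its values were seen, stood at 54.1 against 18.7 CPM. Set against adipocytes with M2, 16 of 24 unfolded protein response genes were higher (21 adjusted over the list alone; adjusted p = 2.35e-10), such as the chaperone HSPA5 at 831 against 583 CPM. Fatty acid oxidation genes were lower in 9 of 20 and higher in 2 (13 and 2 adjusted over the list alone; adjusted p = 5.15e-05, adjusted p = 0.192 with an estimated correlation), with UCP2 at 128 against 196 CPM.

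Metallothioneins and stress genes were high in M1 macrophages: of the oxidative stress and metallothionein list 18 of 23 were higher than in M2 alone and 2 lower (19 and 2 adjusted over the list alone; adjusted p = 4.71e-10, adjusted p = 0.0745 with an estimated correlation), with MT2A at 691 against 3.01 CPM. Dendritic cell markers were higher in 8 of 8 (8 adjusted over the list alone; adjusted p = 9.47e-06, adjusted p = 0.102 with an estimated correlation). In cocultured M1, CCL17, a chemokine of dendritic cells and M2 macrophages, rose from 0.809 to 12.1 CPM. SOX2, a pluripotency factor chosen here after its values were seen, was at 23 and 18.7 CPM in the lone M1 libraries. In cocultured M2, glucocorticoid targets fell in 6 of 14 (6 adjusted over the list alone; adjusted p = 0.000565, adjusted p = 0.213 with an estimated correlation), such as DUSP1, from 25.7 to 5.91 CPM.

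Lists of target genes not named before were used for 3 hypotheses, each tested with camera and an estimated correlation; 5 genes that are also on the unfolded protein response list were taken off the ATF4 list before its test. The rise of PHGDH and PSAT1 in cocultured M1 may be part of a wider ATF4 response to amino acid supply: of 20 other ATF4 targets 7 rose (AARS1, SLC1A5, STC2, SLC1A4, MTHFD1L, DDIT4 and SHMT2) with a median of 0.55. The set test gave p = 0.00352, which met the prediction (1.75e-09 with the preset correlation). It was not repeated without single libraries. PSPH, another enzyme of serine synthesis among the 20, changed by 0.06 (adjusted p = 0.96). The unfolded protein response list, which holds the 5 genes taken off, had 3 of 24 higher and 1 lower in cocultured M1. Adjusted over the list alone these were 6 and 4, with a median of -0.07 and a camera adjusted p = 0.894. Lower activity of YAP, a stretch-responsive coactivator, is a candidate explanation for the fall of ANKRD1, CCN2 and contractile genes in adipocytes with M2. Of 19 other YAP targets 7 fell (median -0.3). The set test, at p = 0.0827, left this undecided (1.03e-08 with the preset correlation). Less BMP signalling could lower ID1 and ID3 in cocultured M2. Of 15 other BMP targets 6 were tested, SMAD7 (-1.17) and ID2 (-0.77) fell, ATOH8 (0.51) rose. The set test, at p = 0.224, left this undecided as well (0.156 with the preset correlation).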
